A study of Mus musculus with 26 samples.

How the data were processed

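Per the labels, total RNA from the lungs of BALB/c mice was labelled with Cy5 and hybridised to CodeLink oligonucleotide arrays, 1 sample per array. The arrays come in 2 formats. The 20K format has 20289 spots, of which 19801 are gene probes. The 10K format has 10500 spots, of which 10012 are gene probes. The labels name 4 groups: control mice ventilated at low pressure, mice given LPS, mice ventilated at high pressure, and mice given both. The 20K format holds 4 control, 5 LPS, 3 high pressure and 5 combined arrays. The 10K format holds 3 arrays for each of the first 3 groups and none for the combined treatment. Pressures, doses and times are not given in the sources used here. The labels do not say that each array is a separate mouse, and they do not say that replicate numbers pair arrays across groups. Names inside the 20K files differ from the labels for 4 arrays. The spot lines of combined replicates 2 and 3 carry the names of LPS replicates 2 and 3, while their headers name the combined treatment. High pressure replicate 3 carries the number 4 inside, and control replicate 1 carries a generic name. Groups follow the labels, and a mix-up of these 4 arrays was not tested.

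Per the file headers, the 10K arrays were read with CodeLink System Software - Analysis 2.3.2 and the 20K arrays with CodeLink Expression Analysis 4.1.0.4163. The deposited scanner files hold spot intensity. On the 20K arrays the raw intensity equals the spot mean minus the median of its local background, checked on the values. On the 10K arrays the raw intensity is already net of background and no background column is given. In both formats the normalized intensity is the raw intensity divided by the array's median, which the authors' scanner software computed. Spots carry quality marks such as good, near background, contaminated, irregular, saturated or masked.

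The deposited value table of 15294 probes holds, for each array, a linear ratio to a level per probe that lies near the median of the control arrays. The exact form of this ratio and its centring are not stated and stay unknown. The column medians were 1.028, 1.015, 1.001 and 1.004 for the 20K controls, 0.986, 0.984, 0.976, 1.009 and 0.996 for 20K LPS, 0.996, 1.01 and 1.017 for 20K high pressure, and 0.982, 0.994, 0.999, 1.019 and 0.99 for the combined treatment. In the 10K columns 5842 values are 0, mostly where a probe is not on that array. Their medians were 0.76, 0.777 and 0.801 for control, 0.722, 0.654 and 0.694 for LPS, and 0.629, 0.7 and 0.524 for high pressure. Over the values above 0 these medians were 0.993, 1.01 and 0.998, then 1.026, 0.998 and 1.021, and then 1.03, 1.015 and 0.996. Across probes, the log2 ratios correlated at 0.783 to 0.93 with the log2 scanner intensity over the control median. Because its form is unknown, the table served only as an alternative.

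The following choices were made before the data were examined. Intensities of the 20K arrays were background-corrected with the normexp model (saddle-point estimate) and an offset of 50. On the 10K arrays values below 0 were set to 0 and 50 was added. Spots marked contaminated, irregular or masked were set to missing and saturated spots were kept. Values were taken to log2 and quantile-normalized within each format. Probes above background on at least 3 arrays of a format were kept, and a probe missing on over 50% of a group's arrays was left out of that group's comparisons. Fold changes are therefore on the scale of log2 of the intensity plus the offset, which shrinks the changes of dim probes.

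Probes were named from their accession through the gene table and platform annotation, before the gene ID of the file. This order was chosen after seeing the data, because the 2 sources named different genes for 405 of 13771 probes. On the 20K format 14837 probes carried a name, for 13955 genes. On the 10K format 9671 probes were named, for 9528 genes. A gene with several probes is represented by the probe with the highest mean intensity. Genome positions are not used here.

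Groups were compared with limma 3.58.1 in R 4.3.3, with 1 fit per format, empirical Bayes moderation and two-sided tests. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a probe passed at an adjusted p below 0.05. Comparisons on the 20K format were each treatment against control, the combined treatment against each single treatment, high pressure against LPS, and the interaction of both. On the 10K format each single treatment was compared with control. The p-values measure the spread between arrays. Near-identical family members can cross-hybridise. The number of arrays limits the precision.

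The lists tested were 35 lists, written beforehand, of inflammatory pathways, stress responses and cell-type markers. Lists with at least 5 measured genes were tested with limma's camera at an inter-gene correlation of 0.01, adjusted over the lists of a comparison. Each was tested again with an estimated correlation. On the 20K arrays 34 lists could be tested and on the 10K arrays 32, since the erythrocyte list had too few measured genes in both formats and the platelet and mesothelial lists had too few on the 10K arrays. Members were also counted at an adjusted p below 0.05 over all probes and adjusted over the list alone.

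Named genes followed a rule. For each treatment against control on the 20K arrays they are the 8 largest rises and the 8 largest falls among named genes that passed, with every treated array on the same side of the control mean. For the other comparisons they are the 5 largest of each. Where none passed, they are the 5 with the smallest p. Genes named for 1 comparison may be followed in the others. Up to 4 members of each list with the smallest p are named, and 6 reference genes (Actb, Gapdh, Hprt, Ppia, Tbp and B2m) are given wherever they were tested. Tbp was missing on 3 of the 5 combined arrays and was not tested there. Genes outside this rule are said to be chosen after their values were seen. Where a gene was near background on every array of a group, the change is given as a bound against the background level.

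The group comparison and the list test were tried on simulated data, the former with known changes in 200 probes. The data were simulated on the normalized scale, so background correction, normalization, filtering and probe naming were not tested. A change of 2 on the log2 scale was recovered for 85% to 98.4% of the changed probes, depending on the comparison. A change of 1 was recovered for 36.7% to 59% in comparisons of groups and for 10.4% in the interaction. In the simulated list test, 1 of 34 lists and 1 of 32 lists passed, the shifted list in both cases. The simulated genes varied independently, so this does not show how the list test behaves with correlated genes.

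Alternatives fixed beforehand were no background correction, plain subtraction, an offset of 16, scaling each array to its median, cyclic loess, no filter on dim probes, a filter that needs signal above background on every array, array weights, a trended and robust fit, a fit of only the groups compared, a minimum change of 2-fold, a block by replicate number, a block by scan batch on the 10K arrays, the deposited value table, and leaving out each array in turn. Further alternatives were chosen after seeing the data. These were contaminated spots kept, a block for the 20K arrays with a median local background above 65, a block for the 20K arrays with a log2 Actb signal below 11, both blocks together, log2 array brightness as a covariate, and the low-Actb arrays left out. Reading and figures used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and Matplotlib 3.10.9. Spots outside the gene probes (controls and blanks) were left out of every comparison.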

Results

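The experiment measured RNA levels in mouse lung after a bacterial stimulus, after injurious ventilation, and after both. Lipopolysaccharide (LPS) is a component of the outer membrane of Gram-negative bacteria that immune receptors detect. The series description attributes the LPS to S. suis, which is Gram-positive, so the identity of the stimulus is unresolved here. High pressure ventilation overstretches the lung, and controls were ventilated at low pressure. The 20K arrays covered control (n = 4), LPS (n = 5), high pressure (n = 3) and LPS plus high pressure, called the combined treatment here (n = 5). The 10K arrays covered control, LPS and high pressure with 3 arrays each.

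Brightness differed between groups on the 20K arrays. The median net intensity per array was 15.8 to 25.7 in controls, 22.05 to 59.8 with LPS, 24.9 to 26.1 with high pressure and 39.2 to 62.7 with the combined treatment. The share of probes near background was 63.2% ± 6.74 (SD, n = 4) in controls, 47.7% ± 12.5 (SD, n = 5) with LPS, 55.8% ± 1.63 (SD, n = 3) with high pressure and 48.1% ± 3.67 (SD, n = 5) with the combined treatment. On the 10K arrays the median net intensity was 15.4 to 36.0 in controls, 19.4 to 26.4 with LPS and 11.5 to 31.0 with high pressure. Local background was 67 to 70 on the combined arrays, 75 on LPS replicate 5 and 60 to 63 on the other 20K arrays. LPS replicate 5 correlated across probes at 0.916 with the combined arrays and at 0.822 with its own group. The first principal components took 24.9%, 14.2% and 13.2% of the variance over 6982 probes.

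**Figure D1:**
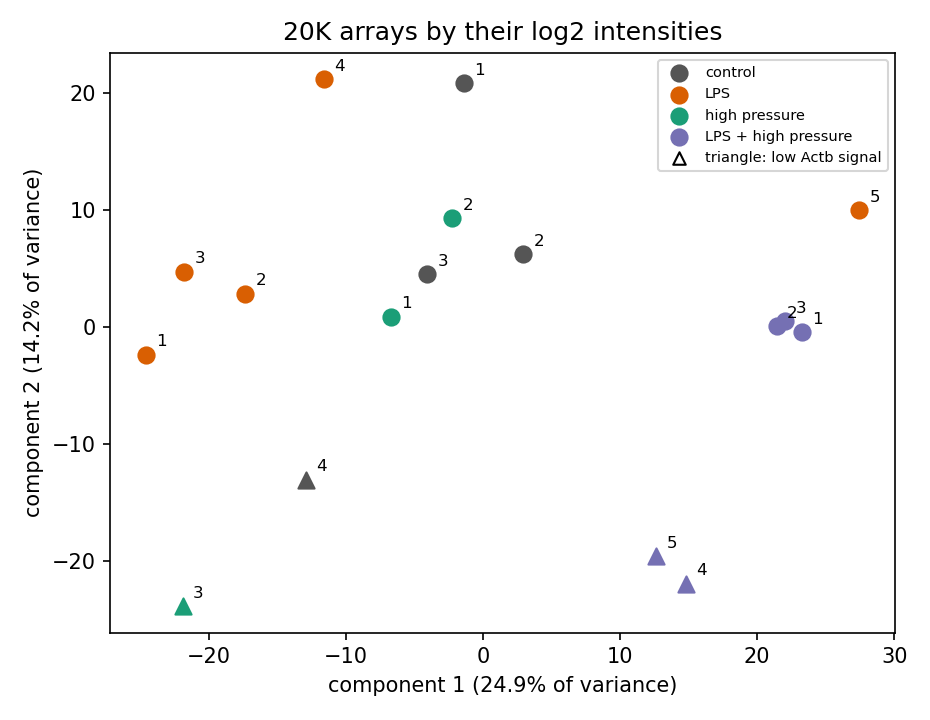
Each point is a 20K array placed by its first principal component (24.9% of the variance) and its second (14.2%), coloured by group. Triangles mark the 4 arrays with a low Actb signal, and LPS replicate 5 lies near the combined arrays.

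A set of 4 arrays on the 20K format had a low signal for the cytoskeletal gene Actb and a high signal for Sftpd, which encodes a surfactant protein. These were control replicate 4, high pressure replicate 3 and combined replicates 4 and 5. Their log2 Actb signal was 8.07 to 9.71 against 12.23 to 13.15 on the other 20K arrays, and their log2 Sftpd signal was 8.75 to 9.44 against 5.96 to 6.82. High pressure replicate 3 of the 10K format showed the same pair of changes, with Actb at 12.19 and Sftpd at 9.38. Whether it shares RNA with the 20K array of that name is not stated. On the 4 arrays 311 of 14499 probes were higher and 131 lower, among them Apoe (2.14 higher) and Gpx1 (2.50 higher), so several reference genes are given for every comparison.

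**Figure D2:**
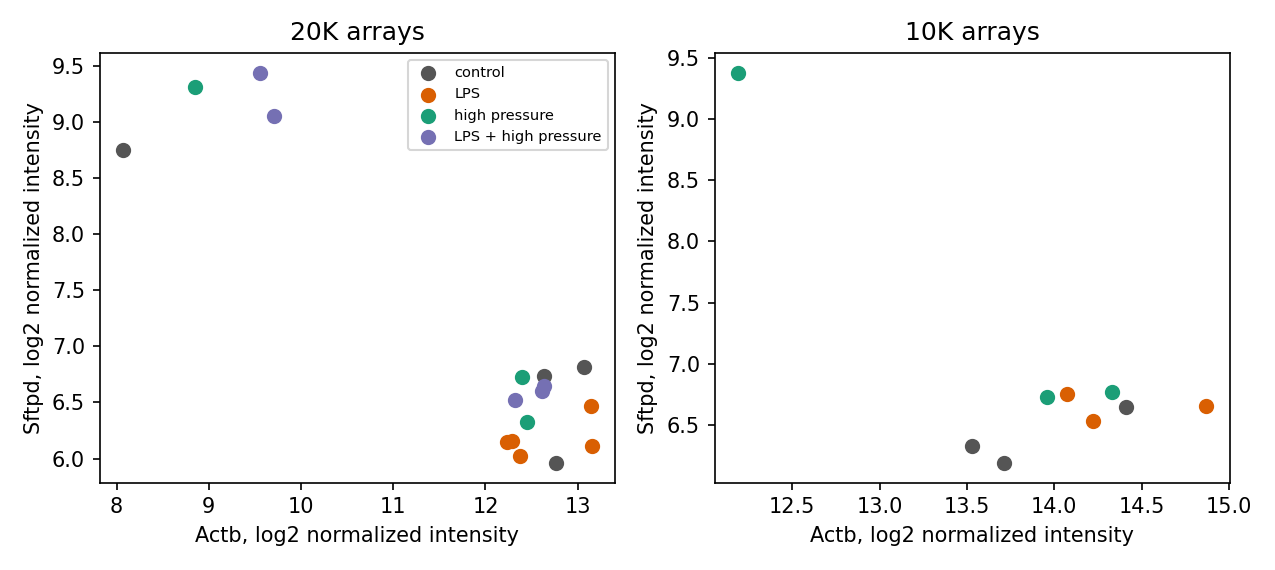
Each point is an array placed by its log2 normalized intensity for Actb and for Sftpd, coloured by group, with the 20K arrays in the left panel and the 10K arrays in the right panel. The 4 arrays at the upper left of the 20K panel have Sftpd at 8.75 to 9.44.

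LPS against low-pressure control on the 20K arrays asks which lung transcripts the bacterial stimulus changed. The cytokine Il6 rose by 2.52 ± 0.29 (SE) on the log2 scale, or 5.75-fold, from 9.32 ± 0.76 (SD, n = 4) to 11.85 ± 0.39 (SD, n = 5), with an adjusted p of 0.000223. The interferon regulator Irf7 rose by 2.11 ± 0.21 (SE), from 10.29 ± 0.13 (SD, n = 4) to 12.41 ± 0.29 (SD, n = 5), with an adjusted p of 4.52e-05. The T-cell attracting chemokines Cxcl11 and Cxcl9 rose by 2.21 and 2.19 (adjusted p 0.00138 and 0.012). The interferon-induced genes Ifit3 and Ifit1 rose by 2.15 and 2.04 (adjusted p 0.00585 and 0.0441). Cep55, a cytokinesis gene, rose by 2.21 and Lhx4, a homeobox gene, by 2.07 (adjusted p 0.000615 and 0.00086). Among the falls were those of the ribosomal protein genes Rps27 (-1.56 ± 0.36 SE, adjusted p 0.0325) and Rps19 (-1.47 ± 0.37 SE, adjusted p 0.0479). The endothelial phosphatase Ptprb fell by 1.62 (adjusted p 0.00493) and Fcgrt, which encodes a receptor for IgG, fell by 1.42 (0.00175). Erh, Tmem234 and Sf3b5 fell by 1.55, 1.55 and 1.38 (adjusted p 0.00534, 0.0313 and 0.0077). The naming rule required each of these genes to lie on the stated side of the control mean on every LPS array measured.

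Interferon-stimulated genes rose as a list after LPS. Their mean change was 0.95 on the log2 scale (median 0.85), with 36 of 39 measured genes higher, in 5 of 5 arrays (adjusted p 7.87e-21, and 0.0396 with an estimated correlation). Of these, 16 rose over all probes tested, 21 rose adjusted over the list alone, and 0 fell. Irf7, Ifih1 (1.96), Ifi47 (1.95) and Oasl1 (2.02) had the smallest p. The NF-kappaB list, regulators and targets of a central inflammatory transcription factor, was higher by a mean of 0.43 in 5 of 5 arrays (adjusted p 0.000343, and adjusted p = 0.352 with an estimated correlation). In it Selp, Nfkb1 and Tnfaip2 rose by 1.34, 1.12 and 1.32, 3 of 24 genes over all probes and 5 adjusted over the list alone. Chemokines were higher by a mean of 0.48 (adjusted p 0.000882, and 0.696 with an estimated correlation), in 5 of 5 arrays but with only 1 of these above every control array. Among 31 chemokines 5 rose over all probes, 8 rose and 1 fell adjusted over the list alone, and Cxcl2 and Ccl7 were 2.02 and 1.51 higher. Proinflammatory cytokines were higher by a mean of 0.40 (adjusted p 0.00293, and 0.189 with an estimated correlation). Only 3 of the 19 rose: Csf2 by 1.90, Il6, and Ebi3, which was at least 1.59-fold higher. Il1b did not pass (0.80, adjusted p 0.165). Macrophage markers were lower by a mean of -0.51, in 16 of 18 genes and 5 of 5 arrays (adjusted p 0.011, and 0.696 with an estimated correlation), but 0 of them passed singly, the nearest being Csf1r (-0.59, adjusted p 0.11) and C1qc (-1.44, adjusted p 0.126). Without LPS replicate 5 the cytokine list had an adjusted p of 0.0629. The macrophage list had 0.252 without control replicate 4 and 0.0537 without LPS replicate 4.

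In all, 132 of 14472 probes rose and 137 fell with LPS (limma), of which 86 and 52 changed at least 2-fold. None of the 6 reference genes passed: Hprt changed by 0.57, Gapdh by -0.15, Ppia by -1.08, Actb by 1.0 and B2m by 0.12, the last turning to -0.20 with median scaling. With the higher local background as a block the fall of Ppia did pass. Tbp was near background on every control array, and its bound (-0.02) allows no direction. The count of 269 changed with the arrays and settings used. It was 167 and 123 without control replicates 1 and 2, 131, 165, 142 and 171 without LPS replicates 1 to 4, and 676 without LPS replicate 5. Median scaling gave 53 higher and 122 lower, and cyclic loess 101 higher and 51 lower. The count was 46 with array brightness as a covariate, 57 with only the 2 groups in the fit, 79 with the deposited values, 145 without the low-Actb arrays and 681 with array weights. With the higher local background as a block 221 were higher and 387 lower, and with a block for low Actb as well 281 and 731, so the balance of rises and falls is not fixed by the data. Of the genes with the largest changes named above, Ifit1, Rps27, Tmem234 and Rps19 did not pass without each array in turn, and the others did.

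**Figure D3:**
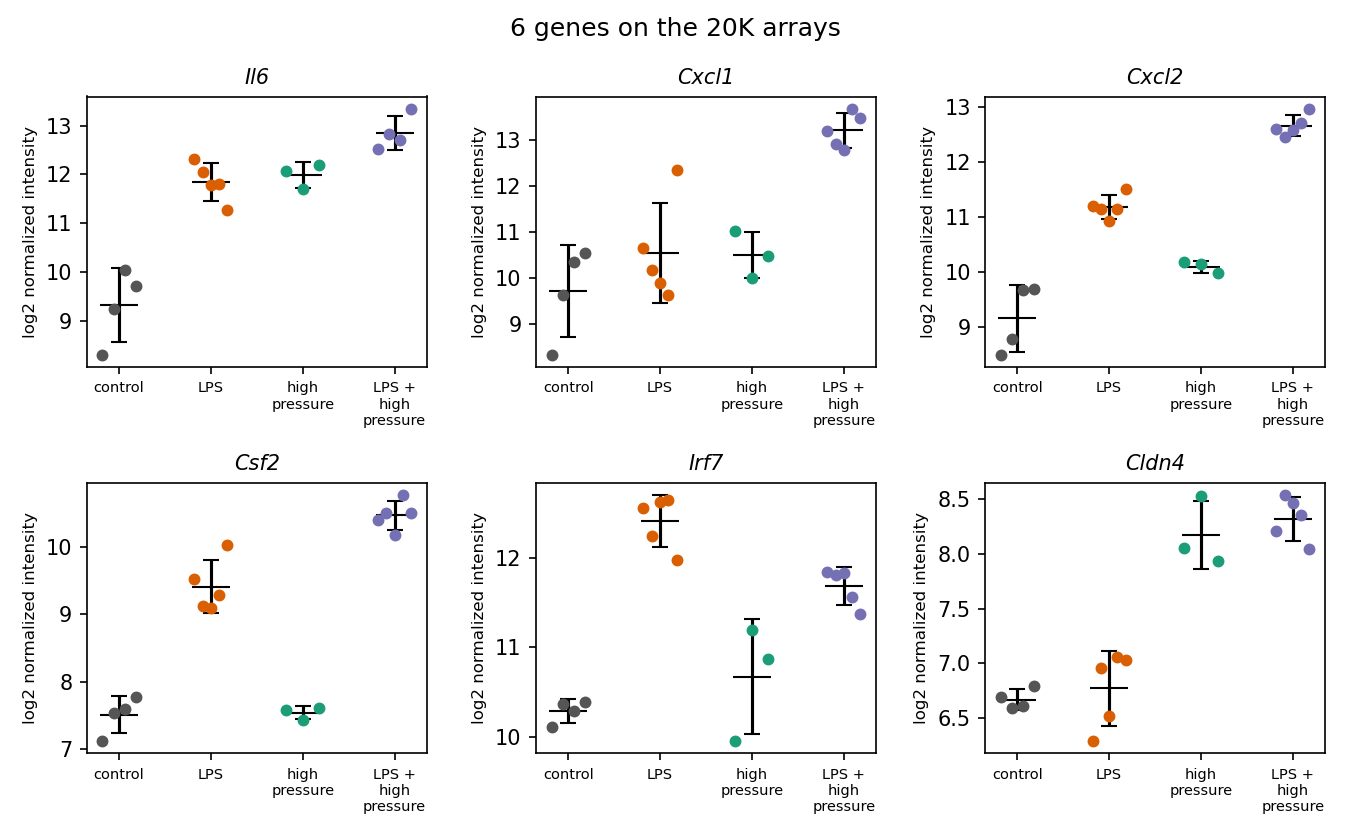
Each point is a 20K array, with log2 normalized intensity of 6 genes on the y axis and the 4 groups on the x axis; bars show the mean ± SD. Il6 lay at 9.32 ± 0.76 in controls and 11.85 ± 0.39 with LPS.

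High pressure against low pressure ventilation on the 20K arrays asks what overstretch alone changed. Il6 rose by 2.66 ± 0.34 (SE), or 6.33-fold, to 11.99 ± 0.26 (SD, n = 3), with an adjusted p of 0.00513. The tight-junction gene Cldn4 rose by 1.51 ± 0.21 (SE), from 6.67 ± 0.09 (SD, n = 4) to 8.17 ± 0.31 (SD, n = 3), with an adjusted p of 0.0062. Errfi1, an inhibitor of EGF receptor signalling, rose by 1.79, Tubb6, a tubulin gene, by 1.81, and Kctd11 by 1.76 (adjusted p 0.0192 for each). Sfn, an epithelial 14-3-3 protein gene, rose by 1.48 and Id3 by 1.22 (adjusted p 0.0392 for both). Ccndbp1 rose by 1.70 (adjusted p 0.0467) and was measured on 2 of the 3 high pressure arrays, where it spread widely (SD 0.98). The ninth probe to pass was that of Ptx3, a secreted pattern-recognition gene (1.19, adjusted p 0.048). All of these except Ptx3 were named by the rule, which required each rise to be seen on every high pressure array measured.

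None of the list shifts with high pressure on the 20K arrays passed with an estimated correlation. Immediate early transcription factors were higher by a mean of 0.33, in 16 of 24 genes and 3 of 3 arrays (adjusted p 0.00041, and 0.216 with an estimated correlation). None of them passed over all probes and 4 did adjusted over the list alone, led by Egr2 (1.14, adjusted p 0.0606) and Nr4a1 (1.49, 0.146). EGF-family and other secreted stretch-associated genes were higher by a mean of 0.33 in 3 of 3 arrays (adjusted p 0.00376, and 0.216 with an estimated correlation), with 4 of 17 adjusted over the list alone and Areg the nearest (1.25, adjusted p 0.0863). Chemokines were higher by a mean of 0.37 in 25 of 31 genes (adjusted p 0.000506, and 0.503 with an estimated correlation), with 4 adjusted over the list alone; without high pressure replicate 3 the adjusted p was 0.51. Feedback inhibitors of cytokine and MAP kinase signalling were higher by a mean of 0.29 (adjusted p 0.00275, and 0.216 with an estimated correlation), where only Errfi1 passed, and had 0.0734 without control replicate 1. Matrix remodelling genes were higher by a mean of 0.35 (adjusted p 0.00848, and 0.294 with an estimated correlation). In that list Timp1 was 1.30 higher without passing (adjusted p 0.127), and the list had 0.0766 without control replicate 1 and 0.301 without high pressure replicate 3. Cytokines were higher by a mean of 0.31 but a median of 0.06, with Il6 the largest change (adjusted p 0.0203, and 0.216 with an estimated correlation). That shift had 0.0659 without control replicate 3 and 0.275 without high pressure replicate 3. Macrophage markers were higher by a mean of 0.28, in 2 of 3 arrays (adjusted p 0.0422, and 0.836 with an estimated correlation). The macrophage shift turned to -0.10 without high pressure replicate 3 (0.83), and had 0.0766, 0.123 and 0.409 without control replicates 1, 2 and 3. Interferon-stimulated genes did not shift with high pressure on the 20K arrays, though they did on the 10K arrays (mean 0.67).

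In all, 9 of 14478 probes rose and 0 fell with high pressure by limma, and 830 probes had an unadjusted p below 0.05. The reference genes had adjusted p of 0.927 or more: Gapdh changed by 0.32, Hprt by 0.43, B2m by 0.14, Ppia by -1.04 and Actb by -0.40, and Tbp, near background on every control array, was at least 1.06-fold higher. The count was 2 without control replicate 1 or high pressure replicate 1, 3 without any of control replicates 2, 3 and 4, and 4 without high pressure replicate 3. Il6 and Cldn4 passed without each array in turn; the other 6 genes named by the rule did not. With only the 2 groups in the fit, 0 probes passed and 635 had an unadjusted p below 0.05. The count was 0 with the deposited values, 1 without the low-Actb arrays, 2 with an offset of 16 and 4 with array brightness as a covariate.

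The combined treatment against control on the 20K arrays asks what both insults changed together. Il6 rose by 3.53 ± 0.31 (SE), or 11.5-fold (n = 4, adjusted p 4.87e-06). The neutrophil-attracting chemokine Cxcl2 rose by 3.50 ± 0.22 (SE), from 9.16 ± 0.61 (SD, n = 4) to 12.67 ± 0.19 (SD, n = 5), with an adjusted p of 4.73e-08. Its relative Cxcl1 rose by 3.50 ± 0.48 (SE, adjusted p 0.000342). The growth factor gene Csf2 rose by 2.95 (adjusted p 4.73e-08), Nfkbia, an inhibitor of NF-kappaB, by 2.57 (0.000497) and Ptx3 by 2.54 (4.94e-07). Car13, a carbonic anhydrase gene, rose by 2.70 (adjusted p 4.87e-06) and Cep55 by 2.40 (0.000136). Among the falls were those of Ypel3 (-1.85 ± 0.16 SE, adjusted p 4.87e-06), the mitochondrial genes Ndufa7 (-1.84, 0.000188) and Fis1 (-1.57, 0.000194), and Pja2 (-1.64, 0.000188). Slc16a9, Thap3, Imp3 and Rasl12 fell by 1.60, 1.56, 1.51 and 1.41 (adjusted p 0.00419, 0.00139, 0.000403 and 0.000929). All 16 passed without each array in turn. That does not address a batch: every combined array and no control array had a median local background above 65. Treatment and such a batch cannot be told apart here, and the background block links these groups only through LPS replicate 5.

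Proinflammatory cytokines had the largest mean rise of the lists under both insults. Their mean change was 0.97 (median 0.60), with 18 of 19 genes higher in 5 of 5 arrays (adjusted p 4.68e-10, and 0.00299 with an estimated correlation). Over all probes 8 of them rose, and 12 rose adjusted over the list alone, among them Il1b (1.78), Csf3 (1.90), Il11 (1.25) and Il23a (0.76). Coagulation and fibrinolysis genes were higher by a mean of 0.57 in 5 of 5 arrays (adjusted p 0.000576, and 0.0224 with an estimated correlation). Tissue factor F3 rose by 2.21, Tfpi2 by 1.78 and F10 by 1.01, 4 of 14 genes over all probes and 6 adjusted over the list alone. NF-kappaB genes were higher by a mean of 0.69 (adjusted p 3.12e-06, and 0.153 with an estimated correlation), with 6 of 24 rising over all probes and 8 adjusted over the list alone, among them Nfkb1 (1.88) and Selp (1.47). Interferon-stimulated genes were higher by a mean of 0.54 (adjusted p 3.12e-06, and 0.247 with an estimated correlation), with 9 of 35 rising, 12 adjusted over the list alone, and Irgm1 (2.32) and Irf7 (1.39) among them. Immediate early factors were higher by a mean of 0.49 (adjusted p 0.00048, and 0.129 with an estimated correlation), with 5 of 24 rising and 7 adjusted over the list alone: Nr4a1 rose by 1.96, Egr2 by 1.03, Zfp36 by 1.26 and Myc by 0.91. EGF-family and stretch-associated genes were higher by a mean of 0.58 (adjusted p 0.00048, and 0.129 with an estimated correlation), with 4 of 17 rising, 8 adjusted over the list alone, and Hbegf (1.99) and Areg (1.56) the largest. These 4 lists were higher in 5 of 5 arrays.

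Some lists moved both ways. Chemokines were higher by a mean of 0.69 (adjusted p 0.00048, and 0.392 with an estimated correlation), with 9 rising and 1 falling over all probes, and 13 rising and 3 falling adjusted over the list alone, of 30. Ccl2 and Ccl11 rose by 1.90 and 1.23, while Ccl6 fell by 1.32 (adjusted p 0.0135). Feedback inhibitors were higher by a mean of 0.45 (adjusted p 0.0108, and 0.313 with an estimated correlation). Errfi1, Socs1 and Spry2 rose by 1.85, 1.82 and 1.24 (Socs1 -0.007 with blocks for local background and low Actb together) and Tsc22d3 fell by 1.15, with 6 rising and 2 falling adjusted over the list alone; without control replicate 1 the list had an adjusted p of 0.0694. Alveolar type 2 cell markers, genes of the surfactant-making epithelium, were lower by a mean of -0.32, in 9 of 11 genes and 4 of 5 arrays (adjusted p 0.00829, and 0.392 with an estimated correlation). Abca3 fell by 0.81 (adjusted p 0.0281), 2 fell adjusted over the list alone, and Cxcl15 did not pass (-0.61, adjusted p 0.0563). The type 2 list had 0.0661 without control replicate 4, one of the low-Actb arrays, and median scaling left a mean of -0.10.

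In all, 382 of 13733 probes rose and 259 fell, of which 207 and 64 changed at least 2-fold. Of the reference genes tested none passed: Hprt changed by 0.41, B2m by 0.17, Ppia by 1.02 (below 0 with the higher local background as a block), Gapdh by -0.04 (0.42 with median scaling and 0.07 with cyclic loess) and Actb by -0.26 (0.10 with median scaling). Median scaling gave 502 higher and 107 lower. The count of 641 was 425 without control replicate 2 and 419, 427 and 425 without combined replicates 2, 4 and 5. It was 13 with array brightness as a covariate and 101 with the higher local background as a block (20 higher and 81 lower, so the balance turned), and in both settings Il6, Cxcl2 and Csf2 passed while Cxcl1, Nfkbia and Cep55 did not. It was 1609 with array weights, 262 without the low-Actb arrays and 194 with both blocks (36 higher and 158 lower). Of the probes tested in both comparisons, 73 rose with LPS and with the combined treatment and 62 fell in both; the shared controls alone make such calls overlap, and the size of that effect was not tested. Of the 9 that rose with high pressure, 8 rose with the combined treatment, the exception being Ccndbp1 (-0.03).

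The combined treatment against LPS alone asks what high pressure added to the bacterial stimulus. Cxcl1 rose by 2.68 ± 0.45 (SE), from 10.54 ± 1.08 (SD, n = 5) to 13.22 ± 0.38 (SD, n = 5), with an adjusted p of 0.00659. Sat1, a polyamine-catabolism gene, rose by 2.13 (adjusted p 0.00253), the ribosomal gene Rps3 by 2.13 (0.0117) and the cytochrome gene Cyp2e1 by 1.97 (0.00558). The reference gene Ppia also rose (2.10, adjusted p 0.0305). With the higher local background as a block none of these 5 passed: the differences were 0.86 for Cxcl1, 0.95 for Sat1, 0.49 for Rps3, 0.60 for Cyp2e1 and -0.32 for Ppia. That block compares the combined arrays only with LPS replicate 5. The interferon regulator Irf1 fell by 1.37 ± 0.28 (SE, adjusted p 0.0173) and the chemokine Ccl19 by 1.27 (0.0133). Ghitm, Pdgfra and Cab39 fell by 1.27, 1.23 and 1.16 (adjusted p 0.0296, 0.0111 and 0.0264). With the block Pdgfra did not pass (-0.78), and the other 4 were missing on LPS replicate 5. Of these 10 genes, 6 passed without each array in turn; the other 4 are Ppia, Irf1, Ghitm and Cab39.

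Interferon-stimulated genes were lower with both treatments than with LPS alone. Their mean difference was -0.44 (median -0.54), in 25 of 35 genes and 5 of 5 arrays (adjusted p 2.37e-06, and 0.242 with an estimated correlation). Irf1, Tgtp1 (-1.09) and Ifi47 (-1.09) fell over all probes, while 13 fell and 1 rose adjusted over the list alone. The difference was -0.13 against LPS replicate 5 and -0.51 against the other 4 LPS arrays. With the higher local background as a block it was -0.19 over 29 genes, and the list call was lost. Cytokines went the other way, with a mean difference of 0.57 (median 0.69) and 15 of 19 genes higher in 5 of 5 arrays (adjusted p 4.95e-05, and 0.0664 with an estimated correlation). Csf3 rose by 1.79, Csf2 by 1.06, Tgfb1 by 1.21 and Il23a by 0.70, 4 over all probes and 12 adjusted over the list alone. EGF-family and stretch-associated genes were higher by a mean of 0.55 (adjusted p 0.000749, and 0.174 with an estimated correlation), with 4 rising (Hbegf 1.71, Areg 1.21, Pdgfa 1.26, Ccn2 1.54) and 9 adjusted over the list alone. Immediate early factors were higher by a mean of 0.45 (adjusted p 0.00387, and 0.239 with an estimated correlation), where Nr4a1 rose by 1.77 and 4 rose adjusted over the list alone. Feedback inhibitors were higher by a mean of 0.45 (adjusted p 0.0111, and 0.296 with an estimated correlation), where Spry2 rose by 1.42 and 6 rose adjusted over the list alone. These shifts too were smaller against LPS replicate 5 than against the other 4 LPS arrays: 0.29 and 0.63 for cytokines, 0.37 and 0.58 for EGF-family genes, 0.15 and 0.50 for immediate early factors, and 0.23 and 0.45 for feedback inhibitors.

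The remaining list shifts against LPS alone no longer passed without some single arrays. Their means were about as large against LPS replicate 5 (macrophage 0.48, adipocyte 0.86, coagulation 0.50) as against replicates 1 to 4 (0.43, 0.87, 0.33). Macrophage markers were higher by a mean of 0.43 (adjusted p 0.0326, and 0.537 with an estimated correlation), with Car4 (1.92) and Fabp4 (1.65) rising and 4 of 18 adjusted over the list alone. That list had an adjusted p of 0.0783 and 0.117 without LPS replicates 4 and 5 and 0.0573 without combined replicate 4. Adipocyte markers, which include Fabp4, were higher by a mean of 0.87, in 6 of 7 genes (adjusted p 0.0351, and 0.537 with an estimated correlation), with Adipoq rising by 1.78 and 4 adjusted over the list alone. They had 0.0674 and 0.118 without LPS replicates 1 and 5 and 0.0898 without combined replicate 3. Coagulation genes were higher by a mean of 0.37 (adjusted p 0.0356, and 0.174 with an estimated correlation), with F3 (1.64) and F10 (0.97) rising and 4 of 14 adjusted over the list alone. They had 0.0926 and 0.14 without LPS replicates 2 and 5, and 0.0617 and 0.113 without combined replicates 2 and 4. All of these lists were higher in 5 of 5 arrays.

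In all, 277 of 13722 probes rose and 68 fell against LPS alone, with 142 and 18 changing at least 2-fold. Other reference genes did not pass: Gapdh differed by 0.12, B2m by 0.05, Actb by -1.27 and Hprt by -0.16 (0.22 with median scaling). Median scaling gave 913 higher and 24 lower and moved the median of all genes to 0.10, and cyclic loess gave 406 higher and 278 lower. The count of 345 was 117, 118, 111 and 107 without LPS replicates 1 to 4 and 1389 without LPS replicate 5. Without combined replicates 1 to 5 it was 196, 156, 163, 101 and 117. With the higher local background as a block, which leaves LPS replicate 5 as the only LPS array in its block, 0 rose and 27 fell, and without the low-Actb arrays 8 passed. The count was 3 with the deposited values, 102 with array brightness as a covariate, 223 with only the 2 groups in the fit and 2394 with array weights. Of the probes that differed, 130 higher and 22 lower ones also differed from control in that direction, in comparisons that share the combined arrays.

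**Figure D4:**
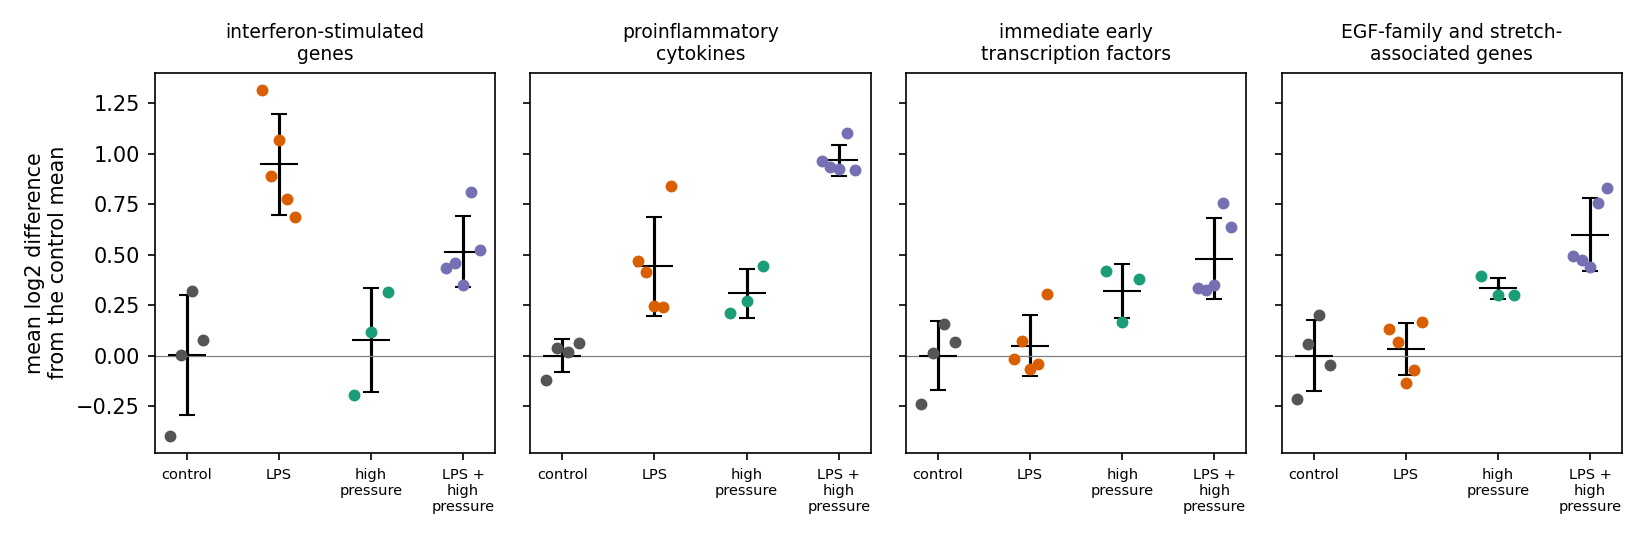
Each point is a 20K array, with the mean log2 difference of a gene list from the control mean on the y axis and the group on the x axis; bars show the mean ± SD. For interferon-stimulated genes LPS replicate 5 lay at 0.69, the other LPS arrays at 0.78 to 1.32 and the combined arrays at 0.35 to 0.81.

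The combined treatment against high pressure alone asks what LPS added to overstretch. Csf2 rose by 2.92 ± 0.21 (SE), from 7.55 ± 0.09 (SD, n = 3) to 10.47 ± 0.21 (SD, n = 5), with an adjusted p of 4.8e-07. Cxcl2 rose by 2.57 ± 0.24 (SE, adjusted p 1.71e-05), Cxcl1 by 2.72 (0.0238), Nfkbia by 2.24 (0.0174) and the granulocyte growth factor gene Csf3 by 2.04 (0.0283). Ccndbp1 fell by 1.74 (adjusted p 0.0158), Ndufa7 by 1.41 (0.0158), Fis1 by 1.15 (0.0226) and Ypel3 by 1.08 (0.0145). Hacd4 was at least 1.95-fold lower and near background on every combined array (adjusted p 0.019). Only Csf2 and Cxcl2 passed without each array in turn. Every combined array and no high pressure array had the higher local background, so added LPS and such a batch cannot be told apart here.

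Cytokines were higher by a mean of 0.66 than with high pressure alone, in 16 of 19 genes (adjusted p 1.86e-06, and 0.0206 with an estimated correlation). Csf2, Csf3, Tgfb1 (1.29) and Il23a (0.82) rose over all probes and 9 rose adjusted over the list alone. Interferon-stimulated genes were higher by a mean of 0.48, in 30 of 35 genes (adjusted p 3.71e-06, and 0.357 with an estimated correlation). Gbp4 (1.67), Irgm1 (1.69) and Irf7 (1.01) rose, and 10 rose adjusted over the list alone. NF-kappaB genes were higher by a mean of 0.54 (adjusted p 6.15e-05, and 0.357 with an estimated correlation), with Nfkbib (1.69), Nfkb1 (1.23), Selp (0.86) and Nfkbia rising over all probes and 5 adjusted over the list alone. Each of these lists was higher in 5 of 5 arrays. In all, 88 of 13727 probes rose and 17 fell, 68 and 5 of them at least 2-fold. Reference genes did not pass: Ppia was 2.06 higher (adjusted p 0.0895, but lower with the background block), Gapdh differed by -0.36, Actb by 0.14, Hprt by -0.03 (0.13 with median scaling) and B2m by 0.03 (-0.04 with cyclic loess). The count of 105 was 19, 56 and 18 without high pressure replicates 1 to 3, and 29, 22, 34, 30 and 43 without combined replicates 1 to 5. Cyclic loess gave 196 higher and 83 lower, and the higher local background as a block gave 1 higher and 12 lower. The count was 2 without the low-Actb arrays, 3 with array brightness as a covariate, 5 with the deposited values, 623 with only the 2 groups in the fit and 902 with array weights.

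High pressure against LPS compares the single insults directly. Csf2 was lower by 1.87 on the log2 scale with high pressure (-1.87 ± 0.21 SE, adjusted p 0.000667), and the interferon-induced genes Irf7 (-1.73 ± 0.23 SE, adjusted p 0.00221), Gbp4 (-1.81, 0.014), Usp18 (-1.85, 0.0203) and Mx2 (-1.72, 0.032) were lower too. Cldn4 was higher by 1.40 ± 0.20 (SE), from 6.77 ± 0.34 (SD, n = 5) to 8.17 ± 0.31 (SD, n = 3), with an adjusted p of 0.00354. Cxxc5 was higher by 1.56 (adjusted p 0.0133, but -0.006 with the deposited values), Ccndbp1 by 1.81 (0.0133), the eosinophil chemokine Ccl24 by 1.18 (0.0431) and Ints6 by 1.15 (0.032). Cldn4, Csf2 and Irf7 passed without each array in turn, and the other 7 genes did not. Il6 did not differ between the single insults (adjusted p 0.915).

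Interferon-stimulated genes were lower with high pressure than with LPS by a mean of -0.87, in 35 of 39 genes and 3 of 3 arrays (adjusted p 1.46e-23, and 0.0242 with an estimated correlation). Over all probes 12 fell and 0 rose, and 19 fell adjusted over the list alone, among them Ifih1 (-1.71) and Samhd1 (-1.16). On the 10K arrays this difference was not seen: against control the list's mean was 0.67 with high pressure and 0.53 with LPS. The single insults were not compared directly on that format. Macrophage markers were higher by a mean of 0.78, in 18 of 18 genes and 3 of 3 arrays (adjusted p 3.05e-07, and 0.245 with an estimated correlation), though only 1 passed adjusted over the list alone. Adipocyte markers were higher by a mean of 0.88 (adjusted p 0.00279, and 0.347 with an estimated correlation), with 4 of 7 adjusted over the list alone and Fabp4 (1.49, adjusted p 0.14) and Retn (1.68, 0.167) the nearest over all probes. NF-kappaB genes were lower by a mean of -0.28 (adjusted p 0.00529, and 0.465 with an estimated correlation), and had 0.073 without high pressure replicate 2. Toll-like receptor genes were lower by a mean of -0.24 (adjusted p 0.0179, and 0.245 with an estimated correlation), with Tlr2 the nearest (-1.0, adjusted p 0.0658). Those had 0.0558 without LPS replicate 5 and 0.124 and 0.073 without high pressure replicates 1 and 2. Feedback inhibitors were higher by a mean of 0.30 (adjusted p 0.0179, and 0.347 with an estimated correlation), and had 0.0563 without LPS replicate 4 and 0.0582 without high pressure replicate 1. Immediate early factors were higher by a mean of 0.29 (adjusted p 0.0242, and 0.347 with an estimated correlation), and had 0.0695 without LPS replicate 3 and 0.149 without high pressure replicate 1. EGF-family and stretch-associated genes were higher by a mean of 0.30 (adjusted p 0.0375, and 0.347 with an estimated correlation), with 3 adjusted over the list alone. Those had 0.053, 0.139 and 0.0637 without LPS replicates 2, 3 and 4, and 0.149 and 0.073 without high pressure replicates 1 and 2. Each list showed its direction in 3 of 3 arrays. In all, 6 of 14466 probes were higher and 22 lower with high pressure, 5 and 21 of them at least 2-fold. Reference genes did not pass: Gapdh differed by 0.47, Actb by -1.41, B2m by 0.02, Tbp by 0.10, Ppia by 0.04 (-0.08 with cyclic loess) and Hprt by -0.13 (0.09 with median scaling). Median scaling gave 5 higher and 2 lower, and blocks for local background and low Actb together gave 52 higher and 29 lower. The count of 28 was 51 without LPS replicate 5 and 13 and 10 without high pressure replicates 1 and 3. It was 0 with only the 2 groups in the fit, 1 with the deposited values, 2 without the low-Actb arrays, 12 with brightness as a covariate and 63 with array weights.

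The interaction tests whether the effect of both insults differs from the sum of the single effects. Atp5g1, a mitochondrial ATP synthase gene, was the only one of 13714 probes to pass, at 2.24 ± 0.28 (SE, adjusted p 0.00502). It lay at 8.39 ± 0.42 (SD) with the combined treatment and 6.57 ± 0.09 (SD, n = 4) with LPS. A further 1643 probes had an unadjusted p below 0.05. Interferon-stimulated genes fell short of the sum, with a mean of -0.50 (median -0.35) and 26 of 35 genes lower (adjusted p 5.19e-05, and 0.971 with an estimated correlation). None of them passed over all probes and 7 were lower adjusted over the list alone, with Ifi47 (-1.56, adjusted p 0.2) and Tgtp1 (-1.33, adjusted p 0.2) the nearest. Median scaling moved the list's mean to -0.17 and the median of all genes to 0.10. The reference genes Ppia, Actb, Hprt, Gapdh and B2m had interactions of 3.13 (adjusted p 0.207), -0.87, -0.59, -0.20 (0.34 with median scaling) and -0.09 (0.34 with median scaling). With the higher local background as a block 0 probes were higher and 8 lower, and Atp5g1, missing on LPS replicate 5, gave no value. Without LPS replicate 5 the count was 608, without LPS replicate 4 it was 3, without combined replicate 5 it was 2, and without high pressure replicates 1 and 2 it was 2 and 3. With cyclic loess or the deposited values it was 0, and with array weights 785.

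On the 10K arrays LPS was compared with control on 3 arrays each. By limma 0 of 5998 probes passed (smallest adjusted p 0.999) and 126 had an unadjusted p below 0.05. That number was 412 without LPS replicate 1 (smallest adjusted p 0.343) and 71 without control replicate 3 (0.209). The genes with the smallest p were Smr2 (0.79 ± 0.15 SE), the interferon-induced Isg20 (1.11 ± 0.24 SE), Heyl (-0.76), Mitd1 (0.78) and Ppp1r14a (-0.99), each with an adjusted p of 0.999 and the stated side on 3 of 3 arrays. Reference genes changed by 0.50 (Actb), -0.54 (Gapdh), 0.40 (B2m), 0.36 (Hprt) and -0.16 (Tbp), and Ppia was not measured in the controls. Interferon-stimulated genes shifted upward here as well, with a mean of 0.53 and 22 of 26 genes higher in 3 of 3 arrays (adjusted p 5.53e-10, and 0.0349 with an estimated correlation), where 2 rose adjusted over the list alone. Ifit1 and Mx2 were 1.95 and 1.54 higher. Adipocyte markers were lower by a mean of -1.39 in 6 of 6 genes and 3 of 3 arrays (adjusted p 1.71e-07, and 0.158 with an estimated correlation), with 5 lower adjusted over the list alone, among them Adipoq (-2.19) and Cfd (-1.99). On the 20K arrays that list was at -0.45 and did not pass (adjusted p 0.243).

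Replicate 1 of each 10K group was read in 1 scan batch and replicates 2 and 3 in another, so each batch holds every group but the first holds only 1 array per group. With scan batch as a block 0 probes passed for LPS and 285 had an unadjusted p below 0.05, and within the second batch 0 passed and 265 did. The LPS shift of interferon-stimulated genes was 0.56 in the first batch and 0.52 in the second (adjusted p 1.47e-08 with the block), and that of adipocyte markers was -1.77 and -1.20 (5.98e-06). Of the other LPS list shifts on these arrays 3 turned sign in the first batch. NF-kappaB genes were higher by a mean of 0.33 (adjusted p 0.000762, and 0.45 with an estimated correlation), but -0.17 in the first batch and 0.58 in the second. EGF-family genes were at 0.30 (0.00367, and 0.255 with an estimated correlation), with -0.14 and 0.47 in the batches, and heat shock genes at 0.28 (0.00856, and 0.245), with -0.12 and 0.47, where the 20K arrays had -0.03 (0.868). Apoptosis regulators were at 0.26 (0.00367, and 0.272 with an estimated correlation), with 0.001 and 0.40 in the batches. Chemokines were at 0.33 (0.00659, and 0.158 with an estimated correlation), with 0.60 and 0.19, and Ccl2 was 1.66 higher. Coagulation genes were at 0.37 (0.0119, and 0.204 with an estimated correlation), with 0.21 and 0.47, and smooth muscle markers at -0.31 (0.0349, and 0.255), with -0.36 and -0.28. None of the genes in these 7 lists passed adjusted over the list alone.

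Those 7 list shifts on the 10K arrays each lost their call without at least 1 array. Without control replicate 3 the adjusted p was 0.0962 for chemokines, 0.0605 for EGF-family genes, 0.0605 for coagulation genes, 0.189 for heat shock genes and 0.087 for smooth muscle markers. Without LPS replicate 2 it was 0.0578 for NF-kappaB genes, 0.0692 for EGF-family genes and 0.151 for apoptosis regulators. Without LPS replicate 3 it was 0.0581 for NF-kappaB genes, 0.237 for coagulation genes, 0.249 for heat shock genes and 0.0912 for smooth muscle markers. Without LPS replicate 1 it was 0.373 for chemokines and 0.374 for smooth muscle markers, and the latter had 0.163 without control replicate 2.

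High pressure against control on the 10K arrays also had 0 of 5999 probes pass by limma, with a smallest adjusted p of 0.149 and 900 probes at an unadjusted p below 0.05. The 5 smallest p belonged to the matrix protease Mmp11 (-1.22 ± 0.16 SE), the monocyte chemokine Ccl2 (3.34 ± 0.43 SE, n = 2), the matricellular gene Ccn1 (1.51 ± 0.22 SE), Pbx2 (-1.27) and Rpl13a (-1.98, n = 2), all with an adjusted p of 0.149. Reference genes did not pass: Actb changed by -0.39, Gapdh by -0.47, B2m by 0.72, Hprt by -0.86 and Tbp by -0.05. Without high pressure replicate 2, 41 probes rose and 228 fell. The 900 probes were 525 without high pressure replicate 3 and 562 without control replicate 3. With scan batch as a block 0 probes passed (1236 with an unadjusted p below 0.05, smallest adjusted p 0.0817), and within the second batch 0 passed (700, smallest 0.36).

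Gene lists shifted by high pressure on the 10K arrays were mostly higher. NF-kappaB genes were higher by a mean of 0.68, in 18 of 19 genes (adjusted p 0.000181, and 0.346 with an estimated correlation), with 1 adjusted over the list alone and Vcam1 2.03 higher. Interferon-stimulated genes were higher by a mean of 0.67 in 21 of 26 genes (adjusted p 0.000181, and 0.169 with an estimated correlation), with 6 higher and 1 lower adjusted over the list alone and Mx2 2.52 higher. EGF-family and stretch-associated genes were higher by a mean of 0.56 (adjusted p 0.000514, and 0.207 with an estimated correlation), with 8 higher and 1 lower adjusted over the list alone: Ccn1 and Areg (1.68) were higher and Pdgfa lower (-1.30). Immediate early factors were higher by a mean of 0.60 (adjusted p 0.000514, and 0.169 with an estimated correlation), with 4 adjusted over the list alone and Klf4 1.35 higher. Oxidative stress genes were higher by a mean of 0.53 (adjusted p 0.00275, and 0.323 with an estimated correlation), with 3 adjusted over the list alone and Gclc 2.07 higher. Fluid transport and junction genes were higher by a mean of 0.57 (adjusted p 0.00639, and 0.169 with an estimated correlation), with 6 adjusted over the list alone, and Sgk1 (1.57) and Cldn4 (0.98) among the higher ones. Apoptosis regulators were at 0.43 (0.00868, and 0.295 with an estimated correlation; Cflar 1.44), matrix remodelling genes at 0.46 (0.00991, and 0.295; Tnc 1.86) and coagulation genes at 0.60 (0.00991, and 0.207; F3 2.03), with 1, 3 and 3 genes higher adjusted over the list alone. Adipocyte markers were lower by a mean of -1.15 (adjusted p 0.00991, and 0.309 with an estimated correlation), with 3 lower adjusted over the list alone and Cfd at -2.73. On the 20K arrays the adipocyte list went the other way with high pressure, without passing (mean 0.42, 6 of 7 genes higher, adjusted p 0.0755). The macrophage markers, higher there, were at -0.07 on the 10K arrays (adjusted p 0.977). All 10 shifts showed their direction in 3 of 3 arrays. On the 20K arrays the lists of immediate early factors, EGF-family genes and matrix genes also passed with high pressure. The lists of NF-kappaB, interferon-stimulated, oxidative stress, fluid transport, apoptosis and coagulation genes did not pass there. Without high pressure replicate 2 the adjusted p was 0.0935 for EGF-family genes and 0.0957 for adipocyte markers.

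The 10 shifts held in sign in both scan batches. In the first and second batch the means were 0.52 and 0.76 for NF-kappaB genes, 0.74 and 0.62 for interferon-stimulated genes, 0.58 and 0.65 for EGF-family genes, and 0.51 and 0.64 for immediate early factors. They were 0.39 and 0.61 for oxidative stress genes, 0.45 and 0.63 for fluid transport genes, 0.37 and 0.46 for apoptosis regulators, 0.35 and 0.48 for matrix genes, 0.62 and 0.58 for coagulation genes, and -1.17 and -1.15 for adipocyte markers. With the block their adjusted p ran from 0.000434 to 0.0212.

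Fold changes were then compared between the formats across genes, which are not independent replicates. The labels reuse sample names in both formats and do not say whether arrays of 1 name share RNA. In their deviations from the group mean, 3 of 9 pairs of the same group and number correlated over 0.1 across formats. Their mean r was 0.028, against -0.01 for other pairs. Whether the formats hold independent samples therefore stays unsettled. For LPS, Pearson's r was 0.291 and Spearman's rho 0.255 over 5313 genes, and 58.2% had the same sign. Among 151 genes that passed on the 20K arrays r was 0.633 and 112 had the same sign (74.2%). Their median size of change was 1.02 on the 20K arrays, on which they were selected, and 0.29 in that direction on the 10K arrays, where 19 of them had the same sign and an unadjusted p below 0.05. For high pressure r was 0.331 and rho 0.288 over 5312 genes, and 7 of the 8 genes that passed on the 20K arrays had the same sign (median size of change 1.60, and 1.36 in that direction on the 10K arrays). Without 20K control replicate 1, r was 0.166 for LPS and 0.162 for high pressure. It was 0.182 for LPS without 10K LPS replicate 3, and 0.215 for high pressure without 20K high pressure replicate 3. With array brightness as a covariate the LPS value was 0.038.

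The LPS and high pressure responses of the 20K arrays share their controls, which alone makes their fold changes correlate. Across 14465 probes r was 0.473, with 66.8% of the same sign and a covariance of 0.0544. Simulated unchanged groups set against the same controls gave a mean r of 0.481 (0.454 to 0.508 over 100 simulations), 66% of the same sign, and a covariance of 0.0377. With separate pairs of controls for each treatment r was 0.03 to 0.231 (mean 0.108 over 6 ways). Il6, Errfi1 and Ptx3 rose with both single insults. With separate pairs of controls 0 to 2 probes did (mean 0.67). These 3 were 1 without control replicate 1, 2 or 4, 1 without LPS replicate 2, and 1 without high pressure replicate 1 or 2.

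Of the 34 lists tested, 18 shifted in at least 1 comparison and 16 in none. The lists without a shift were the markers of B cells, T cells, natural killer cells, neutrophils, platelets, thymus and lymph node, airway epithelium, alveolar type 1 cells, endothelium, mesothelium, and cardiac or skeletal muscle. Cell cycle, eicosanoid, fibrillar collagen, hypoxia and nitric oxide genes did not shift either. Of 302 list tests 60 passed, 50 upward and 10 downward, and 6 passed with an estimated correlation. Those 6 are interferon-stimulated genes with LPS in both formats and in high pressure against LPS, cytokines with the combined treatment against control and against high pressure, and coagulation genes with the combined treatment against control.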

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

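Of the tests in this part, those of a mislabelled sample, of a stronger LPS response, of an array batch for LPS replicate 5, and of a fault of the 20K hybridisation were written after the result was seen.

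A single array lay far from the others of its group in 13 of 192 sets of values, 2 array measures and 11 genes, where chance gives about 1 in 20. The value is the gap to the nearest array divided by the range of the group, on log2 intensities for the genes. In control replicate 1 it was 0.89 for Cep55 (6.55 against 7.37 to 7.47), 0.857 for Rps27 (12.2 against 13.09 to 13.23) and 0.843 for Cyp2e1 (7.72 against 6.94 to 7.06). In control replicate 4 it was 0.971 for Cxcl9 (9.63 against 8.37 to 8.41) and 0.913 for Actb (8.07 against 12.63 to 13.07). In LPS replicate 5 it was 0.867 for the local background (75 against 60 to 62) and 0.965 for the percentage of contaminated probes (13.81 against 0.21 to 0.69). In the same array it was 0.72 for Sf3b5, 0.802 for Ppia (11.71 against 8.38 to 9.04), 0.849 for Rasl12 and 0.846 for Sat1 (7.73 against 6.12 to 6.36). In LPS replicate 4 it was 0.921 for Cab39 (9.34 against 9.93 to 9.99), and in combined replicate 5 it was 0.853 for Ypel3 (8.11 against 8.21 to 8.23).

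The effect of high pressure differed with and without LPS by the interaction test for Atp5g1 (2.24, adjusted p 0.00502, but 0.0766 with cyclic loess and 0.42 with the deposited values) and for the list of interferon-stimulated genes (-0.499, adjusted p 5.19e-05, and 0.971 with an estimated correlation). With the higher local background as a block the interaction had 0 higher and 8 lower probes, and Atp5g1, missing on LPS replicate 5, gave no value.

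LPS replicate 5 lay near the combined arrays, with a correlation across probes of 0.916 against 0.822 with its own group. A mislabelled combined sample is argued against: over the 9 probes raised by high pressure it differed by -0.13 from the other LPS arrays, where the lowest combined array differed by 0.66. A stronger LPS response stays open. Over probes called without LPS replicate 5 and 1 other LPS array, its mean change in the direction of LPS was 0.32 (0.21 to 0.39). The array left out beside it had 0.72 to 1.12. These probes were called from LPS replicates 1 to 4 only, so anything those arrays share favours the array left out. Replicate 5 lay above the other LPS arrays for the cytokine list (0.84 against 0.24 to 0.47). It lay below them for interferon-stimulated genes (0.69 against 0.78 to 1.32). A batch shared with the combined arrays stays open too. The 2457 probes used were unchanged by either single treatment in a fit without LPS replicate 5. Across them that array's difference from LPS replicates 1 and 2 correlated at 0.21 with that of the combined mean from LPS replicates 3 and 4. Another LPS array in its place gave at most 0.12. That array was set against 1 LPS array rather than a mean of 2, so the values are not fully alike. No file names such a batch.

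The 4 arrays with low Actb and high Sftpd came from 3 groups. A fault of the 20K hybridisation alone is argued against for their shared deviation, since 10K high pressure replicate 3 deviated alike across 5336 probes (r 0.40, other 10K arrays at most 0.16), but unevenly: r was 0.518 and 0.434 with combined replicates 4 and 5, 0.264 with high pressure replicate 3 and only 0.185 with control replicate 4, for which such a fault stays open. A larger share of alveolar type 2 cells as the whole cause is argued against: the median deviation of the 10 other markers was 0.18 (median absolute deviation 0.40), where Sftpd deviated by 2.57, although Cd74 (1.69) and Sftpb (0.65) were higher too. That median exceeded 0.15, the 95th percentile of random lists and the bound written before the test, so a small change in that share is not excluded; the comparison with Sftpd was chosen after. RNA or labelling differences along the transcript stay open: different probes of 1 gene deviated alike at r 0.11 over 595 pairs, against 0.21 for the combined treatment, and no biological explanation other than the cell share was tested.

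Interferon-stimulated genes were lower with both treatments than with LPS alone (-0.44, SD over genes 0.60). Array brightness as the whole cause is argued against, since the difference was -0.55 with brightness as a covariate (p 1.01e-09). A batch stays open: with the higher local background as a block the difference was -0.19 (SD over genes 0.46, p 0.0116, adjusted p 0.0805), so the list call ended. The block leaves LPS replicate 5 as the only LPS array beside the combined arrays and 29 of 35 genes measured, and which of these ended the call was not separated from the smaller difference. A biological effect of high pressure on the interferon response was not tested apart from that batch, and the difference from the other 4 LPS arrays was -0.51.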

How the results depend on the processing

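The tests with blocks for local background, low Actb or both, with array brightness, without the low-Actb arrays, with contaminated spots kept and with scan batch for the gene lists were chosen only after the data were seen. Of 347 named gene results under the alternatives, 7533 of 8588 values kept direction and side of the threshold, 792 no longer passed, 128 newly passed, and 131 changed sign without passing in either setting. The cause was not tested for any count below, except where fewer arrays or the 2-fold bound lower it by construction. Low signal limits all of this: 48.1% to 63.2% of probes were near background in the combined and control groups, so fold changes of dim genes are compressed. For the counts of probes, the arrays left out are those of the groups compared; the fit shares its spread with the other groups, whose arrays were not left out for these ranges.

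LPS against control had 269 probes past the threshold. It had 175 with median scaling, 152 with cyclic loess, 681 with array weights, 138 at 2-fold or more, 57 with only the 2 groups in the fit and 79 with the deposited values. It had 608 with the background block (221 higher, 387 lower), 1012 with both blocks (281 higher, 731 lower), 46 with brightness and 145 without the low-Actb arrays. Leaving out an array gave 123 to 676.

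High pressure against control had 9. It had 2 with offset 16, 5 with median scaling, 0 with only the 2 groups (635 at unadjusted p below 0.05), 4 with brightness, 1 without the low-Actb arrays and 0 with the deposited values (936 at unadjusted p below 0.05). Leaving out an array gave 2 to 9.

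The combined treatment against control had 641. It had 1609 with array weights, 271 at 2-fold or more, 101 with the background block (20 higher, 81 lower), 194 with both blocks (36 higher, 158 lower), 13 with brightness and 262 without the low-Actb arrays, and 419 to 607 on leaving out an array.

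The combined treatment against LPS had 345. It had 226 with offset 16, 937 with median scaling, 684 with cyclic loess, 2394 with array weights, 160 at 2-fold or more, 223 with only the 2 groups and 3 with the deposited values. It had 27 with the background block and 26 with both blocks (0 higher in each), 102 with brightness and 8 without the low-Actb arrays. Leaving out an array gave 101 to 1389.

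The combined treatment against high pressure had 105. It had 31 with offset 16, 279 with cyclic loess, 195 for probes above background on every array, 902 with array weights, 623 with only the 2 groups and 5 with the deposited values. It had 13 with the background block (1 higher, 12 lower), 196 with the low-Actb block, 20 with both (2 higher, 18 lower), 3 with brightness and 2 without the low-Actb arrays. Leaving out an array gave 18 to 56.

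High pressure against LPS had 28. It had 10 with offset 16, 7 with median scaling, 61 for probes above background on every array, 63 with array weights, 0 with only the 2 groups (1086 at unadjusted p below 0.05) and 1 with the deposited values. With both blocks it had 81 (52 higher, 29 lower), 12 with brightness and 2 without the low-Actb arrays, and 10 to 51 on leaving out an array.

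The interaction had 1 and no value with only the 2 groups. It had 0 with cyclic loess (1717 at unadjusted p below 0.05), 785 with array weights, 8 with the background block (0 higher), 8 with both blocks (0 higher) and 0 with the deposited values (1526 at unadjusted p below 0.05). Leaving out an array gave 1 to 608. For the 10K format LPS had 0 throughout, and high pressure 0 to 269 on leaving out an array.

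Of 302 list tests 60 passed; 39 did with the background block, 6 with an estimated correlation, and 55 to 62 on leaving out an array. The correlation of the formats across genes was 0.291 for LPS, 0.038 with brightness, 0.186 with the deposited values and 0.166 to 0.339 on leaving out an array. For high pressure it was 0.331, 0.223 with brightness and 0.162 to 0.401. The overlap of the LPS and high pressure responses was 3 probes. It was 1 with offset 16 or median scaling, 6 for probes above background on every array or with both blocks, and 0 with only the 2 groups, without the low-Actb arrays or with the deposited values. With controls divided it was 0, 0, 0, 1 and 1 in 5 ways and 2 in the sixth, and 1 to 4 on leaving out an array.

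Direction turned for Ppia in the combined treatment against LPS (-0.32 with the background block, -0.027 with both), Socs1 in the combined treatment against control (-0.007 with both blocks) and Cxxc5 in high pressure against LPS (-0.006 with the deposited values). Of the lists only 1 turned without high pressure replicate 3, namely alveolar and interstitial macrophage markers, high pressure versus control, 20K arrays, where leaving out an array gave an adjusted p of 0.000287 to 0.83 (0.0422 with all arrays).

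The labels do not say that replicate numbers pair the samples. With a replicate block the counts were 4 for high pressure, 354 for the combined treatment, 5 for it against high pressure, 8 for high pressure against LPS and 1 for the overlap. On the 20K arrays 5 of 22 pairs with the same number correlated over 0.1 (mean -0.035) and 2 of 17 arrays correlated best with their own number. In the 10K format 7 of 9 pairs correlated over 0.1 (mean 0.286, lowest 0.053, other pairs -0.142) and 7 of 9 arrays correlated best with their own number. Number 1 is also the first scan batch there, so a pairing in that format stays unsettled, and with the replicate block both 10K counts stayed at 0.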

Other observations

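Of the tests in this part, those with a background or low-Actb block were chosen only after the data were seen, and the other groupings of the arrays were planned before.

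Groupings of the same arrays show how often a count as large arises without the real grouping. Each tally counts the real grouping as 1 of those drawn. For LPS against control 4 of 100 gave 269 or more probes (highest other 698), for the combined treatment against control 1 of 100 gave 641 (highest other 48), and for the combined treatment against LPS 3 of 100 gave 345 (highest other 794). For the combined treatment against high pressure 1 of 56 gave 105 (highest other 48), and for high pressure against LPS 2 of 56 gave 28 (highest other 85). By a bound of 1 in 20 set before the test, chance is excluded for each of these 5 counts taken alone. The number of counts examined was not allowed for, and 3 of the 5 were exceeded by another grouping. These groupings cannot separate the combined treatment from a batch by local background. Chance is not excluded for high pressure against control, where 2 of 35 gave 9 (highest other 32), nor for the interaction, where 10 of 100 gave 1 or more (highest other 357). On the 10K arrays the 10 groupings of each comparison are too few, with a real count of 0 for LPS (highest other 0) and 0 for high pressure (highest other 1).

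The groupings with the highest counts point to a structure of the samples. For LPS that grouping set LPS replicate 5 with the 4 controls, and the count with the background block was 608. For the combined treatment against LPS it set combined replicate 5 with LPS replicates 1 to 4, and the count with that block was 27. For high pressure against control it joined 2 low-Actb arrays, control replicate 4 and high pressure replicate 3, with control replicate 1, and the count with the low-Actb block was 9. For high pressure against LPS it set LPS replicate 5 with high pressure replicates 1 and 2, and the count with the background block was 37. For the combined treatment against high pressure it set the low-Actb arrays apart from the others. These are high pressure replicate 3 and combined replicates 4 and 5, and the low-Actb block raised the count of that comparison.

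On LPS replicate 5 the mean difference from control was 0.84 for cytokines, where the other LPS arrays had 0.24 to 0.47 and the combined arrays 0.92 to 1.1. For immediate early factors it was 0.30, against -0.07 to 0.07 on the other LPS arrays and 0.33 to 0.76 on the combined arrays. Other lists placed that array with its own group: adipocyte markers were at -0.45 (other LPS arrays -0.83 to -0.26, combined arrays 0.23 to 0.71) and macrophage markers at -0.49 (-0.80 to -0.34 and -0.25 to 0.23). These 4 of 34 lists were chosen after their values were seen.

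On the low-Actb arrays Tspo, Gpx4 and Ear2 were higher by 1.76, 1.78 and 2.25, and the type 2 cell markers Cd74 and Sftpb by 1.69 and 0.65 (adjusted p 0.00574 and 0.0344). Chil1 differed by 1.98 (adjusted p 0.0605), Sftpc by 0.17, Sftpa1 by -0.08 and Abca3 by -0.45.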
